A study of Mus musculus with 16 samples.

How the data were processed

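The series holds 16 RNA sequencing libraries from sorted mouse lung AT2 cells. Per the labels' protocols, lungs were digested to single cells, cells with CD45 or CD31 were depleted, and live AT2 cells were gated as negative for CD45, CD31 and CD104, positive for Epcam and high for CD200, then separated by CD44. Libraries came from a stranded total RNA kit with ribosomal RNA removal, per the labels' protocols. The values are raw counts per gene as deposited, whole numbers with no normalization. Reads were aligned with Bowtie2 to mm10, per the submitters' processing notes, which give no version. No label or header gives the counting program, the annotation or the strand setting, so reads of a gene and an overlapping antisense gene cannot be told apart.

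The sorts were taken from the column names, which state CD44- or CD44+. The genotypes were not: the columns carry the prefixes R26 and OG with animal numbers, the labels give genotypes by title only, and the treatment text OG TMX stands on all 16 samples, so the OG prefix does not mark mutants through the labels. R26 was read as control because Rosa26 is a common site for recombinase alleles, which is background knowledge and close to a guess. The order of columns matched the order of titles but was not used. No expression value was used to assign a genotype. If the reading is wrong, every OG against R26 difference and the interaction change sign against genotype, while the CD44 comparisons stand.

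Gene identifiers were matched to symbols for 25275 of 27179 identifiers (93.0%). Identifier 100861531, which has no symbol in the reference tables, held 7.32% of all counts and stayed in the table. Coordinates are from an mm10 (GRCm38) annotation. Library totals were 9022471 to 21363816, so that 3 counts, the floor used for low genes, correspond to at most 0.333 CPM. Counting limits cover counting error only, since reads were not marked by molecule.

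Tests used R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, and the robust quasi-likelihood F test on 1 mean per group over all 16 libraries, with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. The SE of a log2 fold change is its size divided by the square root of F. The 32 gene lists, 770 genes of which 30 stand on more than 1 list, were written before the data were examined and tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted over the 32 lists in each of 5 comparisons. camera with an estimated correlation and fry were run beside it. With the estimated correlation, calls held for 1 list in OG CD44+ against CD44-, 1 in each OG against R26 comparison, and 0 in the others. Named genes are the sorting antigens and Sftpc, the 8 largest changes each way among called genes with mean log2 CPM of at least 4 and no overlap of the groups (5 each way for the interaction, where overlap was not asked about). Predicted or unnamed genes, pseudogenes, ribosomal RNA and small RNAs were passed over. Up to 4 members per described list with the smallest adjusted p were added, and members in the minority direction were allowed as exceptions. That rule was also set before the data were examined, and not every gene it takes is printed. A list's median, mean and test differed in sign for mesothelial markers in OG CD44+ against CD44-, and for lysosome, glycolysis and MHC class II lists in R26. They also did for NF-kappaB, lymphocyte and erythroid lists between prefixes in CD44- cells and fibroblast markers in CD44+ cells. In the interaction they did for lysosome, NF-kappaB, mesenchymal, Wnt and Notch, basal, neutrophil and sorting antigen lists.

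Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, at least 50 counts in 4 libraries, only the 8 libraries compared, a replicate block, a 1.5-fold minimum, limma voom with quality weights, and leaving out each library. Leaving out both libraries of OG animal 3, voom with 1 weight per group, and TMM against other reference libraries were added after seeing the data. Each comparison was repeated on all 35 splits of its libraries, or of the 8 animals for the interaction.

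Data were simulated with the real means and library sizes (15516 genes, 200 changed), with the compared groups otherwise equal. All groups had 1 spread per gene, and far fewer genes changed than were called in the real data, so recovery there may differ. For OG CD44+ against CD44-, edgeR recovered 93.9% of 66 scored 2-fold changes and 66.7% of 33 scored 1.5-fold changes. For R26 it recovered 95.5% and 78.8%. For OG against R26 it recovered 98.5% and 85.2% in CD44- cells and 92.4% and 61.1% in CD44+ cells. With simulated animal effects of SD 0.2 in log2, 2-fold interaction changes were recovered at 53.0% without a block and 75.5% with it. The simulation first required edgeR to recover over 80% of 2-fold changes in every comparison. That bound was limited to comparisons of 2 groups after the interaction missed it. Of 200 random lists, camera gave p under 0.05 for 1, 4, 1 and 1 in these comparisons. The simulated genes varied independently of each other, unlike real lists, such as cell cycle in R26 with an estimated correlation of 0.58. These shares therefore do not show how often camera at the preset correlation gives false calls on the real lists.

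CD44- and CD44+ libraries with the same prefix and animal number were taken as pairs from 1 animal, since the series text counts 4 lungs per genotype and each gave both sorts. That the sorts share animals was written before the data were examined; giving blocked values beside the results they change was decided after the blocked fits were seen. Deviations from the group means correlated within pairs at 0.46, 0.37, 0.47 and 0.23 for R26 animals 8, 7, 2 and 1, and at 0.27, 0.01, 0.14 and 0.15 for OG animals 7, 6, 5 and 3. Each CD44- library except that of OG animal 6 correlated best with the CD44+ library of its own pair.

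Spread between replicates, as a biological coefficient of variation, was 6.41% in R26 CD44-, 14.6% in R26 CD44+, 3.93% in OG CD44- and 8.37% in OG CD44+ cells. No sample was left out.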

Results

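RNA was sequenced from alveolar type 2 (AT2) cells, the surfactant-making epithelial cells of the lung, sorted from 8 mice as CD44- and CD44+ fractions, which gave 16 libraries in 4 groups of 4. The sort took cells without surface CD45, CD31 and CD104, with Epcam and high CD200, and then split them by CD44. The count table names its columns by the prefixes R26 and OG, 4 animals each, and the groups carry those names here: R26 CD44-, R26 CD44+, OG CD44- and OG CD44+. The labels list control and Sftpc mutant lungs but do not tie either prefix to a genotype, and they give all 16 samples the same treatment text, OG TMX. Reading R26 as control and OG as mutant is an inference and could be wrong. The comparisons of CD44+ with CD44- cells inside a prefix do not depend on it. Total counts ran from 9022471 to 21363816 per library, and 15516 genes were tested. Levels are CPM, counts scaled to library size, as mean ± SD with n = 4. Differences are log2 fold changes ± SE from edgeR. The first 4 principal components took 56.6%, 24.7%, 5.08% and 2.93% of the variance.

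Sftpc, which encodes surfactant protein C and is the gene named in the genotype labels, was an abundant transcript in every group (gene 20389, chromosome 14, 70520941 to 70524081 in mm10). It stood at 79592 ± 7872 CPM in R26 CD44- cells, 54364 ± 12252 in R26 CD44+ cells, 11684 ± 432 in OG CD44- cells and 6696 ± 684 in OG CD44+ cells. The Sftpc level checks no genotype, since the labels do not describe the mutation. Cd44, the hyaluronan receptor used for the last gate (gene 12505, chromosome 2, 102811141 to 102901669), was at 329 ± 4.45, 469 ± 77.4, 562 ± 24.1 and 914 ± 22.6 CPM in the same order. Itgb4, which encodes the CD104 used to exclude cells, was at 6.78 ± 0.378, 13.8 ± 4.10, 24.9 ± 1.80 and 94.7 ± 5.64 CPM. Cd200, by contrast, was at 178 ± 9.39, 134 ± 9.37, 123 ± 3.66 and 78.2 ± 2.38 CPM. Ptprc, which encodes CD45, was at 0.164 ± 0.0279, 7.94 ± 5.06, 1.21 ± 0.329 and 5.14 ± 2.33 CPM, with 9 counts in total over the 4 R26 CD44- libraries.

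**Figure D1:**
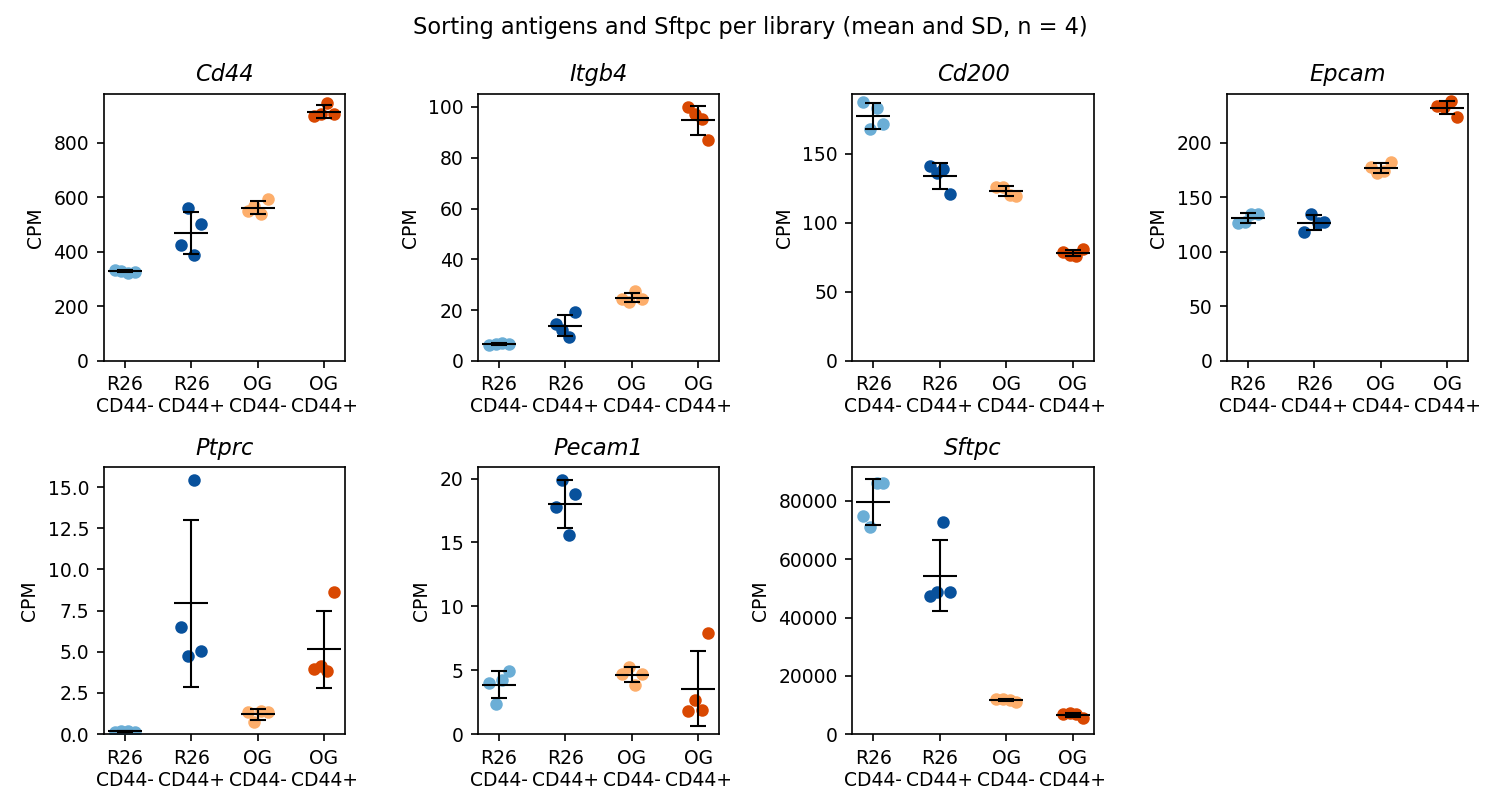
CPM (vertical axes from 0) of the sorting antigens and Sftpc in each library, by group; bars give the mean and SD of 4 libraries. Cd44 and Itgb4 are highest in OG CD44+ libraries, and the mean of Sftpc is highest in R26 CD44- cells.

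The first comparison asks how CD44+ cells differ from CD44- cells within the OG prefix. The series names this contrast in fibrotic lungs as its question, which these libraries address only if OG marks the mutants. OG CD44+ cells had lower levels of AT2 genes: in the list of AT2 identity and surfactant genes, of 30 tested, 3 rose and 27 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.88. The AT2 identity and surfactant list had camera adjusted p = 9.50e-13, and adjusted p = 0.126 with an estimated correlation. Lyz2, a lysozyme made by AT2 cells, fell from 5387 ± 321 to 1081 ± 27.9 CPM (log2 fold change -2.32 ± 0.10, adjusted p = 3.88e-14), and further log2 fold changes were Lamp3 -1.39 ± 0.06, Ppp1r14c -1.37 ± 0.05 and Sftpc -0.80 ± 0.11. Lyz1 and Lyz2 are close copies, so how reads were divided between them is uncertain. Markers of the transitional, Krt8-high alveolar state moved the other way: of 34 tested, 24 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.44. The transitional alveolar list had camera adjusted p = 8.56e-10, and adjusted p = 0.126 with an estimated correlation. Among them Cldn4, a tight junction claudin, went from 343 ± 6.77 to 801 ± 47.3 CPM (log2 fold change 1.22 ± 0.08, adjusted p = 1.48e-10), Krt19 changed by 0.60 ± 0.04, and Sprr1a fell by 1.48 on the log2 scale. In the AT2 list the members that rose included Ctsh, a cathepsin, by 0.42 ± 0.06, and Dlk1, a Notch ligand, by 2.06 ± 0.29.

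Lists of mesenchymal, profibrotic, YAP and TAZ, interferon and p53 genes were higher in OG CD44+ cells, as were cell cycle and AT1 lists, and all 7 were higher in R26 CD44+ cells too. Fibroblast and mural markers rose in the same sorts, as given below, and which cells carried the mesenchymal and profibrotic transcripts was not measured. For the mesenchymal transition and cytoskeleton list, of 33 tested, 27 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.53. The mesenchymal transition and cytoskeleton list had camera adjusted p = 9.53e-14, and adjusted p = 0.0402 with an estimated correlation. Actin crosslinker Actn1 changed by 0.84 ± 0.04 and the membrane metalloprotease Mmp14 by 1.19 ± 0.07. For profibrotic ligands and the TGF-beta pathway, of 30 tested, 24 rose and 1 fell (24 and 2 adjusted over the list alone), with a median log2 fold change of 0.78. The profibrotic ligands and TGF-beta pathway list had camera adjusted p = 1.37e-10, and adjusted p = 0.0901 with an estimated correlation. Its members included the ligands Pdgfb 1.13 ± 0.07, Ereg 1.23 ± 0.11 and Tgfb2 1.05 ± 0.09. For YAP and TAZ targets, of 25 tested, 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 0.68. The YAP and TAZ targets list had camera adjusted p = 8.78e-08, and adjusted p = 0.063 with an estimated correlation. Its members included Ccn2 1.97 ± 0.12 and Axl 1.39 ± 0.10. For interferon response genes, of 33 tested, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.71. The interferon response list had camera adjusted p = 3.80e-07, and adjusted p = 0.126 with an estimated correlation. Its members included the GTPase Gbp2 at 1.35 ± 0.13. For p53 targets and senescence, of 27 tested, 15 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.18. The p53 targets and senescence list had camera adjusted p = 0.00166, and adjusted p = 0.0746 with an estimated correlation. For the cell cycle list, of 40 tested, 10 rose and 0 fell (2 and 0 adjusted over the list alone), with a median log2 fold change of 0.49. The cell cycle list had camera adjusted p = 2.31e-04, and adjusted p = 0.463 with an estimated correlation. For AT1 markers, of 22 tested, 13 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.28. The AT1 markers list had camera adjusted p = 5.56e-04, and adjusted p = 0.292 with an estimated correlation.

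Unfolded protein response, NRF2 and fatty acid lists were lower in OG CD44+ cells, and immediate early genes were higher. For the unfolded protein response, of 30 tested, 2 rose and 19 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.29. The unfolded protein response and ER stress list had camera adjusted p = 1.59e-05, and adjusted p = 0.063 with an estimated correlation. Its members included Ern1, the IRE1 sensor, at -0.56 ± 0.05 and Trib3 at -1.03 ± 0.09. For NRF2 and oxidative stress genes, of 26 tested, 1 rose and 17 fell (1 and 18 adjusted over the list alone), with a median log2 fold change of -0.35. The NRF2 and oxidative stress list had camera adjusted p = 1.02e-05, and adjusted p = 0.128 with an estimated correlation. Its members included Srxn1 at -0.79 ± 0.06 and the cystine transporter Slc7a11 at -0.75 ± 0.07. For fatty acid and phospholipid synthesis, of 28 tested, 3 rose and 21 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.34. The fatty acid and phospholipid synthesis list had camera adjusted p = 7.37e-05, and adjusted p = 0.239 with an estimated correlation. Its members included the acyltransferase Gpam at -0.91 ± 0.06. For cholesterol synthesis, of 23 tested, 2 rose and 10 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.21. The cholesterol synthesis list had camera adjusted p = 0.261, and adjusted p = 0.747 with an estimated correlation. For immediate early and heat shock genes, of 29 tested, 18 rose and 4 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.38. The immediate early and heat shock list had camera adjusted p = 0.00152, and adjusted p = 0.425 with an estimated correlation.

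Markers of other cell types moved with the OG CD44+ sort, in both directions. For ciliated cell markers, of 20 tested, 19 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.85. The ciliated cell markers list had camera adjusted p = 3.87e-12, and adjusted p = 0.126 with an estimated correlation. Its members included Tmem212 at 1.92 ± 0.15. For club and secretory markers, of 14 tested, 12 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.85. The club and secretory cell markers list had camera adjusted p = 4.51e-08, and adjusted p = 0.063 with an estimated correlation. Its members included Scgb3a1 at 2.65 ± 0.17. For fibroblast and mural markers, of 27 tested, 23 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.95. The fibroblast and mural cell markers list had camera adjusted p = 3.44e-09, and adjusted p = 0.128 with an estimated correlation. Its members included Sparc at 0.60 ± 0.06 and Pdgfrb at 1.13 ± 0.13. For endothelial markers, of 23 tested, 2 rose and 12 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.68. The endothelial cell markers list had camera adjusted p = 0.0401, and adjusted p = 0.466 with an estimated correlation. Its members included Cdh5 at -1.47 ± 0.21 and Esam at -0.73 ± 0.05. With the animals as a replicate block the endothelial list lost its call (adjusted p = 0.079), and so it did without OG CD44+ of animal 7, 6 or 5 (adjusted p = 0.0603 to 0.0822). Pecam1, which encodes CD31, stood at 4.65 ± 0.598 and 3.55 ± 2.92 CPM (adjusted p = 0.374 by edgeR), and without the OG animal 3 CD44+ library its log2 fold change was -1.16 (adjusted p = 1.44e-04, and up to 0.688 over all alternatives). For mesothelial markers, of 6 tested, 2 rose and 4 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.95. The mesothelial cell markers list had camera adjusted p = 0.959, and adjusted p = 0.97 with an estimated correlation, where the test pointed up and the median down. For lymphocyte markers, of 11 tested, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00355, adjusted p = 0.283 with an estimated correlation). For basal cell markers, of 10 tested, 3 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.239 with an estimated correlation), and for neutrophil, mast cell and eosinophil markers, of 5 tested, 3 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.126 with an estimated correlation). The basal call was lost without OG animal 5 CD44+ (adjusted p = 0.0532). Macrophage and monocyte markers missed the threshold: of 24 tested, 8 rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.358, adjusted p = 0.611 with an estimated correlation). So did erythroid and platelet markers, of 6 tested, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.308, adjusted p = 0.39 with an estimated correlation), and neuroendocrine and tuft cell markers, of 8 tested, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.521, adjusted p = 0.575 with an estimated correlation).

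Genes named for the size of their change, here and below, are called genes with mean log2 CPM of at least 4, and genes given with their lists are not repeated. Plasma cell transcripts were among the largest increases in OG CD44+ cells: Igha 4.59 ± 0.49, Jchain 4.38 ± 0.42, Igkc 4.37 ± 0.47 and Ighg2c 2.65 ± 0.65. Immunoglobulin constant genes share sequence, so their separate counts are uncertain. Other large increases were Muc5b 2.87 ± 0.21, Ctse 2.69 ± 0.16, Sdc3 2.45 ± 0.11 and Anxa8 2.38 ± 0.18, where Muc5b is an airway mucin. Large decreases, besides lysozymes, were Acoxl -2.64 ± 0.18, Anpep -2.24 ± 0.15, Itih4 -1.81 ± 0.11, Hc -1.78 ± 0.06, Chia1 -1.75 ± 0.14 and Mme -1.73 ± 0.06. Among the gate antigens, Cd44 changed by 0.70 ± 0.08, Epcam by 0.39 ± 0.05, Itgb4 by 1.93 ± 0.11, Ptprc by 2.12 ± 0.39 and Cd200 by -0.65 ± 0.05. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3464 higher and 4351 lower in OG CD44+ cells, of which 1730 and 269 differed at least 2-fold. Of these calls, 1483 higher and 362 lower passed a test against a 1.5-fold minimum. Which direction held more calls without a fold minimum was not settled: 3903 were higher and 3451 lower with OG animal 7 CD44- as the scaling reference. In a fit of only these 8 libraries, which can only scale to an OG library, 4283 were higher and 3918 lower. The median gene shifted by 0.0615 in that fit, and by 0.0559 with the OG animal 7 CD44- reference. Other causes were not tested. Without any 1 of the 8 R26 libraries, 3830 to 4098 were higher and 3474 to 3816 lower.

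The second comparison asks the same of R26 cells. AT2 genes were lower in R26 CD44+ cells as well: of 30 tested, 1 rose and 27 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.50. The AT2 identity and surfactant list had camera adjusted p = 1.68e-16, and adjusted p = 0.0538 with an estimated correlation. Surfactant protein D gene Sftpd went from 2371 ± 89.5 to 1677 ± 84.8 CPM (log2 fold change -0.50 ± 0.05, adjusted p = 1.19e-07), Sftpc changed by -0.55 ± 0.11 and the transcription factor gene Etv5 by -0.69 ± 0.07. Dlk1, the AT2 list member that rose, had 1 count in total over the 4 R26 CD44- libraries. Markers of alveolar type 1 (AT1) cells, the thin gas-exchange cells, were higher: of 22 tested, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.77. The AT1 markers list had camera adjusted p = 3.13e-12, and adjusted p = 0.0538 with an estimated correlation. Its members included Spock2 2.09 ± 0.08 and Pdpn 1.96 ± 0.09, while Aqp5 was at -0.36 ± 0.08. For transitional markers, of 34 tested, 25 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.57. The transitional alveolar list had camera adjusted p = 3.13e-12, and adjusted p = 0.0538 with an estimated correlation. Its members included Cldn4 at 2.94 ± 0.14 and Krt19 at 1.08 ± 0.05.

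Markers of every other cell type examined had medians above 0 in the R26 CD44+ sort. For fibroblast and mural markers, of 27 tested, 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 2.56. The fibroblast and mural cell markers list had camera adjusted p = 4.77e-19, and adjusted p = 0.0522 with an estimated correlation, and the collagen gene Col3a1 went from 35.4 ± 7.05 to 342 ± 130.1 CPM. For endothelial markers, of 23 tested, 22 rose and 1 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 2.21. The endothelial cell markers list had camera adjusted p = 8.06e-13, and adjusted p = 0.0522 with an estimated correlation. Its members included Cdh5 2.81 ± 0.19 and Plvap 2.47 ± 0.24 and Pecam1 at 2.23 ± 0.35. For mesothelial markers, of 6 tested, 6 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.99. The mesothelial cell markers list had camera adjusted p = 1.55e-05, and adjusted p = 0.0522 with an estimated correlation. For club markers, of 14 tested, 10 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.57. The club and secretory cell markers list had camera adjusted p = 6.92e-05, and adjusted p = 0.0926 with an estimated correlation. Its members included Scgb3a1 at 2.05 ± 0.18. For ciliated markers, of 20 tested, 13 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.49. The ciliated cell markers list had camera adjusted p = 5.54e-05, and adjusted p = 0.266 with an estimated correlation. Its members included Tmem212 at 1.56 ± 0.22.

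Blood-cell lists were higher in R26 CD44+ cells by camera at the preset correlation. For lymphocyte markers, of 11 tested, 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.00e-04, adjusted p = 0.124 with an estimated correlation). For macrophage and monocyte markers, of 24 tested, 13 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00359, adjusted p = 0.131 with an estimated correlation), and Itgam, an integrin of myeloid cells, went from 0.163 ± 0.0703 to 5.33 ± 1.46 CPM. For neutrophil, mast cell and eosinophil markers, of 5 tested, 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.0538 with an estimated correlation). For erythroid and platelet markers, of 6 tested, 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.0538 with an estimated correlation), and for neuroendocrine and tuft cell markers, of 8 tested, 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.0538 with an estimated correlation). For basal cell markers, of 10 tested, 4 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.127, adjusted p = 0.323 with an estimated correlation). Plasma cell transcripts were again among the largest increases, with Jchain going from 1.38 ± 0.563 to 203 ± 64.3 CPM, Igkc from 6.78 ± 3.22 to 927 ± 490.1 and Igha from 9.11 ± 3.64 to 1180.0 ± 471.

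**Figure D2:**
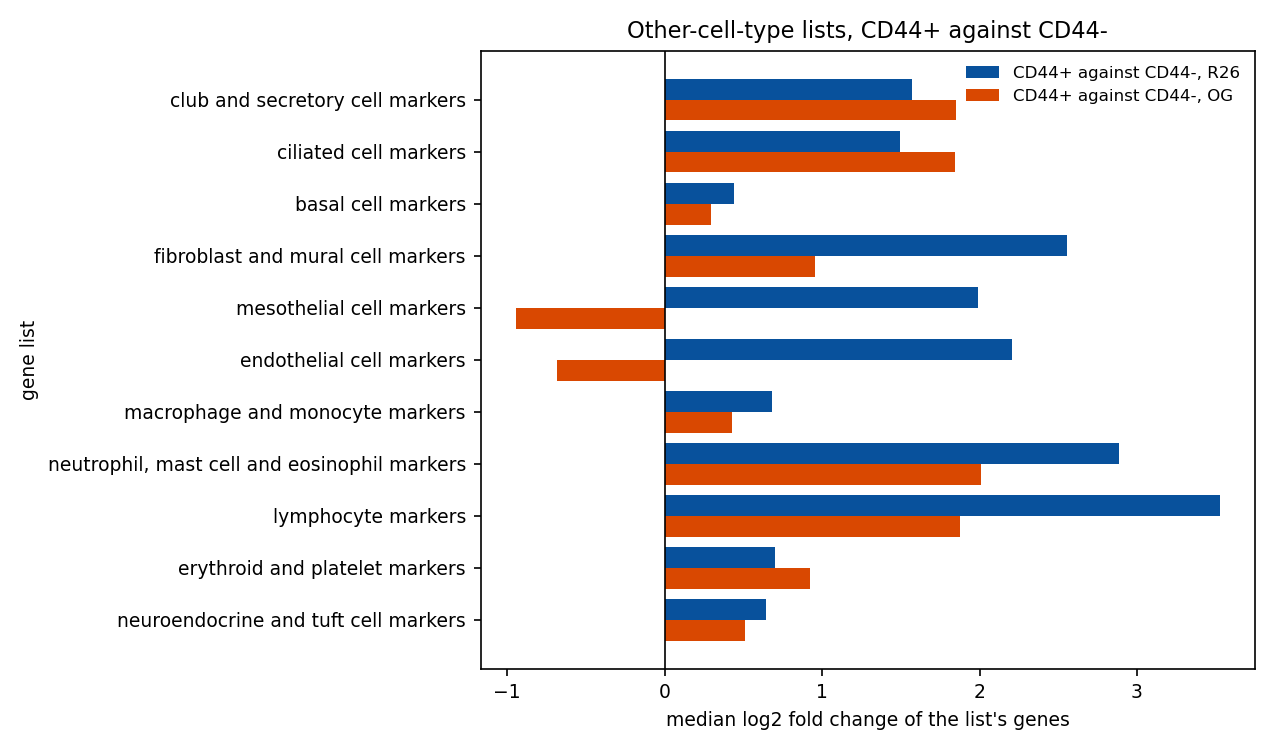
Median log2 fold change (horizontal axis) of each other-cell-type marker list between CD44+ and CD44- cells, for R26 and OG libraries, over genes with more than 3 counts in each group compared. All 11 R26 bars lie above 0, and the OG bars for mesothelial and endothelial markers lie below it.

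Lists given above for OG CD44+ cells had these values in R26. For the mesenchymal transition and cytoskeleton list, of 33 tested, 26 rose and 2 fell (27 and 3 adjusted over the list alone, camera adjusted p = 7.35e-11, adjusted p = 0.0522 with an estimated correlation). For profibrotic ligands and the TGF-beta pathway, of 30 tested, 21 rose and 0 fell (22 and 0 adjusted over the list alone, camera adjusted p = 9.91e-10, adjusted p = 0.0553 with an estimated correlation). For YAP and TAZ targets, of 25 tested, 16 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 1.09e-06, adjusted p = 0.0522 with an estimated correlation). For interferon response genes, of 33 tested, 19 rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 8.01e-07, adjusted p = 0.106 with an estimated correlation). For p53 targets and senescence, of 27 tested, 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 4.22e-04, adjusted p = 0.0522 with an estimated correlation). For immediate early and heat shock genes, of 29 tested, 10 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.48 with an estimated correlation). That call was lost by fry (adjusted p = 0.0532) and without R26 animal 2 CD44-, animal 7 CD44+ or animal 1 CD44+ (adjusted p = 0.0771 to 0.111). For the unfolded protein response, of 30 tested, 4 rose and 10 fell (4 and 11 adjusted over the list alone, camera adjusted p = 0.0279, adjusted p = 0.181 with an estimated correlation). For fatty acid and phospholipid synthesis, of 28 tested, 1 rose and 17 fell (1 and 19 adjusted over the list alone, camera adjusted p = 4.49e-07, adjusted p = 0.113 with an estimated correlation). For NRF2 and oxidative stress genes, of 26 tested, 13 rose and 5 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.112, adjusted p = 0.485 with an estimated correlation).

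The cell cycle list was higher in R26 CD44+ cells, as it was in OG CD44+ cells at the preset correlation. For the cell cycle list, of 40 tested, 28 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 fold change of 1.54. The cell cycle list had camera adjusted p = 2.99e-09, and adjusted p = 0.223 with an estimated correlation. Its members included Ccnb1 2.83 ± 0.30 and Plk1 2.49 ± 0.26. Cholesterol synthesis genes were lower: of 23 tested, 0 rose and 19 fell (0 and 20 adjusted over the list alone), with a median log2 fold change of -0.37. The cholesterol synthesis list had camera adjusted p = 3.64e-09, and adjusted p = 0.124 with an estimated correlation. Its members included Idi1 at -0.48 ± 0.08. Other large increases in R26 CD44+ cells were Igfbp4 3.51 ± 0.19, Dcn 3.34 ± 0.12, Mmp2 3.34 ± 0.38 and Eln 3.22 ± 0.30, all genes of the matrix or its growth factor binding, and the receptor kinase Axl was at 3.03 ± 0.12. Large decreases included Pla2g1b -0.98 ± 0.15, Prag1 -0.89 ± 0.09, Tmem42 -0.76 ± 0.08, Notum -0.75 ± 0.09, Sfta2 -0.73 ± 0.10, Bex4 -0.72 ± 0.11 and Cdh16 -0.71 ± 0.09. Cd44 changed by 0.51 ± 0.08, Itgb4 by 1.05 ± 0.15, Ptprc by 5.50 ± 0.53 and Cd200 by -0.40 ± 0.05. Epcam was at -0.05 ± 0.05 (adjusted p = 0.481 by edgeR), and it was lower with adjusted p from 0.0103 to 0.037 without R26 animal 8 CD44-, animal 7 CD44-, animal 7 CD44+ or animal 2 CD44+. Over all alternatives its adjusted p ran from 0.0103 to 0.871.

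In all, edgeR called 3357 genes higher and 2393 lower in R26 CD44+ cells, of which 2245 and 23 differed at least 2-fold, and 2026 and 9 passed the 1.5-fold minimum. The number of lower genes rested on the scaling reference: it was 4824 with OG animal 7 CD44- as the reference. It was 3647 to 4429 without any 1 of 7 R26 libraries (all CD44-, and CD44+ of animals 8, 7 and 2), which also moved the reference. Of the genes higher in OG CD44+ cells, 2145 were also higher in R26 CD44+ cells (749 for independent lists), and of the lower ones, 1436 were also lower (671 for independent lists). Across genes, which are not independent replicates, the log2 fold changes of the sort correlated between prefixes with Pearson r = 0.72 and Spearman rho = 0.543.

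The third comparison sets OG against R26 within CD44- cells. OG reads as mutant and R26 as control only under the unverified reading above. OG CD44- cells had transitional alveolar genes at far higher levels: of 34 tested, 32 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.88. The transitional alveolar list had camera adjusted p = 4.02e-13, and adjusted p = 0.116 with an estimated correlation. Cldn4 went from 2.64 ± 0.609 CPM in R26 to 343 ± 6.77 in OG (log2 fold change 6.997 ± 0.12, adjusted p = 1.13e-20), the lectin gene Lgals3 from 55.1 ± 3.07 to 669 ± 39.4, and Krt19 from 62.0 ± 2.46 to 425 ± 8.79, while Ndrg1 was at 3.61 ± 0.06. AT2 genes were lower: of 30 tested, 4 rose and 26 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -1.21. The AT2 identity and surfactant list had camera adjusted p = 2.27e-11, and adjusted p = 0.175 with an estimated correlation. Its members included Sftpc -2.77 ± 0.12, Hc -2.10 ± 0.06 and Bex2 -4.00 ± 0.12, and Ctsh at 1.19 ± 0.06 among the few that rose. AT1 markers were higher: of 22 tested, 19 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.17. The AT1 markers list had camera adjusted p = 1.25e-08, and adjusted p = 0.175 with an estimated correlation. Its members included Pdpn 2.99 ± 0.09 and Clic5 1.99 ± 0.06.

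Stress programs separated the prefixes in CD44- cells, which are genotypes only by the unverified reading. For p53 targets and senescence, of 27 tested, 22 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.39. The p53 targets and senescence list had camera adjusted p = 8.83e-07, and adjusted p = 0.0182 with an estimated correlation. Its members included Ccng1 2.20 ± 0.05 and Phlda3 3.66 ± 0.09, and Btg2 fell by 1.73 on the log2 scale. For NRF2 genes, of 26 tested, 23 rose and 1 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.503. The NRF2 and oxidative stress list had camera adjusted p = 1.03e-09, and adjusted p = 0.116 with an estimated correlation. Its members included Srxn1 5.15 ± 0.08, Gclm 3.53 ± 0.08 and Gpx2 4.31 ± 0.10. Slc7a11 went from 0.965 ± 0.318 to 597 ± 38.0 CPM, the largest named log2 fold change at 9.24 ± 0.13 (adjusted p = 4.94e-22). For the unfolded protein response, of 30 tested, 21 rose and 7 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.56. The unfolded protein response and ER stress list had camera adjusted p = 0.00407, and adjusted p = 0.175 with an estimated correlation. Its members included the asparagine synthetase gene Asns at 3.14 ± 0.09 and Herpud1 at -0.90 ± 0.05. For profibrotic ligands, of 30 tested, 20 rose and 4 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.20. The profibrotic ligands and TGF-beta pathway list had camera adjusted p = 6.02e-04, and adjusted p = 0.366 with an estimated correlation. Its members included Spp1 7.03 ± 0.17 and Gdf15 2.41 ± 0.08.

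Metabolic genes differed as well between OG and R26 CD44- cells, whose genotypes the labels do not tie to prefixes. For nuclear oxidative phosphorylation subunits, of 36 tested, 31 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.59. The nuclear oxidative phosphorylation subunits list had camera adjusted p = 4.67e-06, and adjusted p = 0.175 with an estimated correlation. Its members included Uqcrq at 1.57 ± 0.08. For cholesterol synthesis, of 23 tested, 1 rose and 21 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -1.23. The cholesterol synthesis list had camera adjusted p = 8.19e-11, and adjusted p = 0.175 with an estimated correlation. Its members included Idi1 -2.11 ± 0.09 and Insig1 -2.30 ± 0.10. For lysosome and autophagy genes, of 31 tested, 19 rose and 6 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.25. The lysosome and autophagy list had camera adjusted p = 0.0109, and adjusted p = 0.366 with an estimated correlation. For MHC class II, of 9 tested, 1 rose and 8 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.72. The MHC class II list had camera adjusted p = 0.00176, and adjusted p = 0.366 with an estimated correlation. Its members included H2-Ab1 at -0.94 ± 0.07. For immediate early and heat shock genes, which also respond to tissue dissociation, of 29 tested, 7 rose and 21 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -1.49. The immediate early and heat shock list had camera adjusted p = 2.34e-05, and adjusted p = 0.366 with an estimated correlation. Its members included Fos -2.99 ± 0.08, Ier2 -2.54 ± 0.07, Egr1 -3.63 ± 0.13, Fosb -3.54 ± 0.24 and Nr4a1 -3.18 ± 0.18, whereas Myc was at 1.52 ± 0.09.

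Again with genotype unverified, other large increases in OG CD44- cells were Ptprn 6.95 ± 0.11, Kif1a 6.88 ± 0.11, Sprr1a 5.87 ± 0.24 and Tnfrsf21 4.71 ± 0.14, and large decreases, besides those given with their lists, were Tmem132d -4.54 ± 0.11, Gem -4.01 ± 0.15, Mgll -3.94 ± 0.28, Lyz1 -3.72 ± 0.09 and Tent5a -3.41 ± 0.08. Among the antigens, Cd44 changed by 0.77 ± 0.08, Epcam by 0.43 ± 0.05, Itgb4 by 1.88 ± 0.13, Cd200 by -0.53 ± 0.05 and Ptprc by 2.78 ± 0.65, while Pecam1 was at 0.29 ± 0.36 (adjusted p = 0.5 by edgeR). Fibroblast markers moved with the prefix: of 27 tested, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 1.32. The fibroblast and mural cell markers list had camera adjusted p = 3.44e-04, and adjusted p = 0.366 with an estimated correlation. For ciliated markers, of 20 tested, 17 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.13. The ciliated cell markers list had camera adjusted p = 0.0109, and adjusted p = 0.597 with an estimated correlation. For basal cell markers, of 10 tested, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.193 with an estimated correlation). No other list of other-type markers passed at the preset correlation with all libraries. Endothelial markers (adjusted p = 0.0933) passed without R26 CD44- of animal 2 or 1, or R26 CD44+ of animal 8, 2 or 1 (adjusted p = 0.0279 to 0.0464). By fry, the club list pointed down, and endothelial, macrophage, mesothelial, neutrophil and neuroendocrine lists pointed up (adjusted p = 9.45e-07 to 0.00863). fry does not compare a list with other genes, and 69.0% of all genes were called here. Of 14 club markers 2 rose and 4 fell, of 23 endothelial 12 and 1, and of 24 macrophage 16 and 3. Of 6 mesothelial markers 2 rose and 0 fell, of 5 neutrophil 1 and 0, and of 8 neuroendocrine 4 and 2. edgeR called 6113 genes higher and 4592 lower in OG CD44- cells, 2129 and 1764 of them at least 2-fold, with 2551 and 2095 past the 1.5-fold minimum. The median log2 fold change of all genes was 0.12, and with OG animal 7 CD44+ as the scaling reference it shifted by -0.11. The excess of higher genes went with it, to 5170 higher and 5386 lower. Without any 1 of the 8 R26 libraries, 4874 to 5346 were higher and 5140 to 5523 lower.

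**Figure D3:**
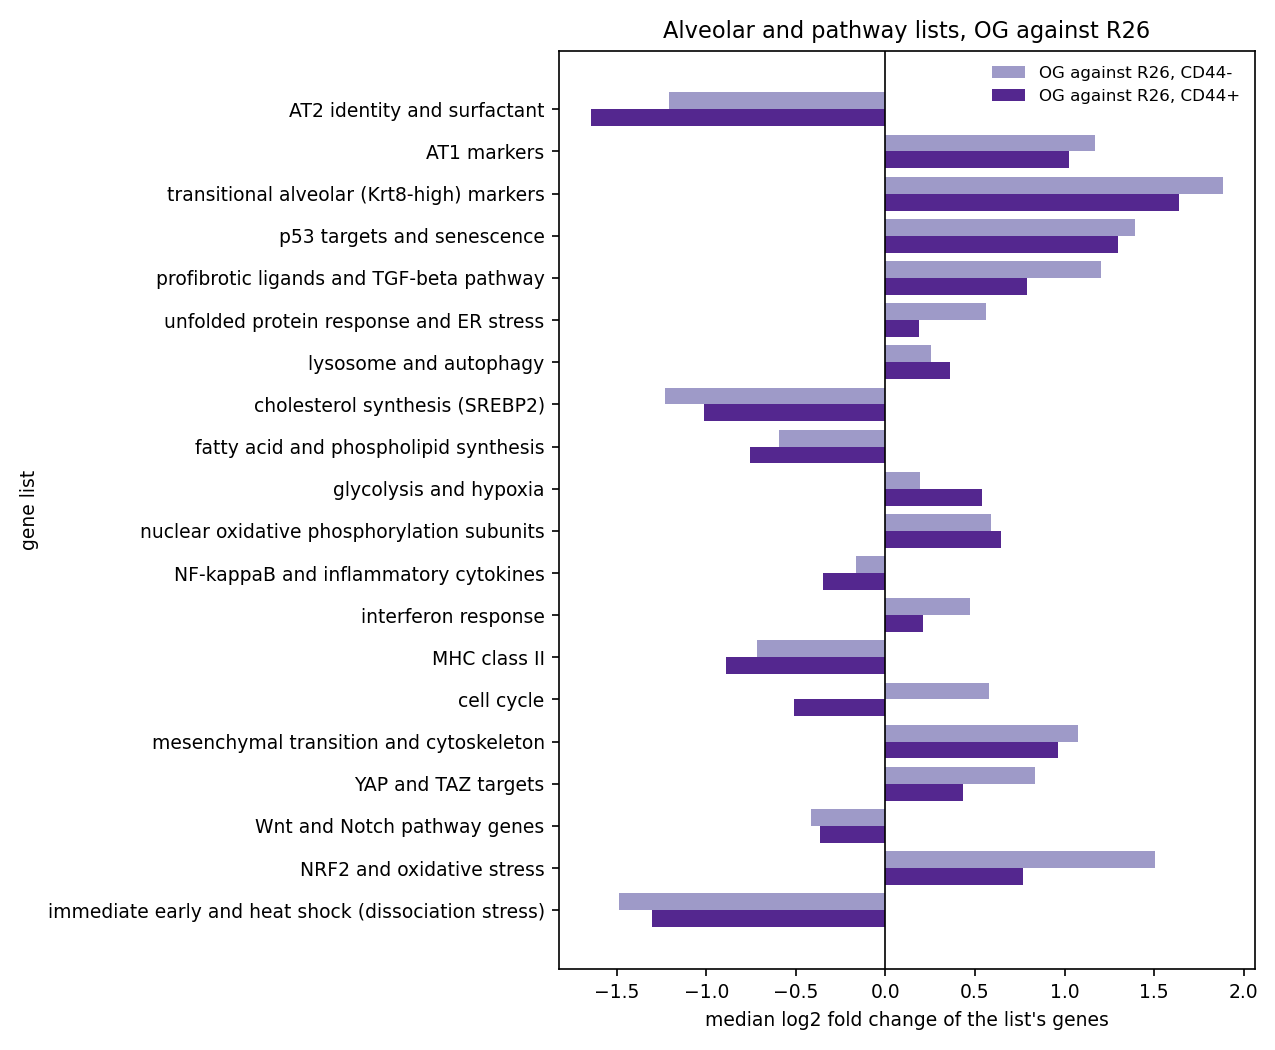
Median log2 fold change (horizontal axis) between OG and R26 libraries of the tested genes of each alveolar and pathway list, for CD44- and CD44+ cells. Transitional, p53 and NRF2 lists lie above 0 in each sort, and AT2, cholesterol synthesis and immediate early lists lie below it.

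The fourth comparison sets OG against R26 within CD44+ cells. OG reads as mutant and R26 as control only under the unverified reading above. Every tested transitional gene was higher in OG CD44+ cells: of 34 tested, 34 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.64. The transitional alveolar list had camera adjusted p = 6.89e-17, and adjusted p = 0.0776 with an estimated correlation. Clu, a secreted chaperone, went from 516 ± 83.8 to 8511 ± 121 CPM (log2 fold change 4.04 ± 0.09, adjusted p = 4.74e-20), Cldn4 from 20.5 ± 3.87 to 801 ± 47.3, and Lgals3 and Krt19 changed by 3.03 ± 0.06 and 2.30 ± 0.05. For the AT2 list, of 30 tested, 3 rose and 26 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -1.64. The AT2 identity and surfactant list had camera adjusted p = 2.74e-11, and adjusted p = 0.228 with an estimated correlation. Its members included Sftpc -3.02 ± 0.12, Hc -3.46 ± 0.07, Lamp3 -2.03 ± 0.06 and Lyz2 -4.09 ± 0.10, and Ctsh at 2.00 ± 0.06. Lyz1, which stands on the macrophage list, was at -5.76 ± 0.10. For AT1 markers, of 22 tested, 17 rose and 5 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.03. The AT1 markers list had camera adjusted p = 8.65e-05, and adjusted p = 0.273 with an estimated correlation. Spock2 fell by 1.89 on the log2 scale.

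Several programs that separated OG from R26 CD44- cells also separated the CD44+ cells, with the same doubt on genotype. For p53 targets, of 27 tested, 20 rose and 3 fell (21 and 3 adjusted over the list alone), with a median log2 fold change of 1.30. The p53 targets and senescence list had camera adjusted p = 6.93e-07, and adjusted p = 0.0157 with an estimated correlation. Its members included Ccng1 2.18 ± 0.05, Cdkn1a 1.62 ± 0.06 and Btg2 -1.45 ± 0.08. For NRF2 genes, of 26 tested, 22 rose and 1 fell (24 and 1 adjusted over the list alone), with a median log2 fold change of 0.77. The NRF2 and oxidative stress list had camera adjusted p = 6.17e-09, and adjusted p = 0.13 with an estimated correlation. Its members included Slc7a11 6.23 ± 0.11 and Srxn1 3.51 ± 0.08. For profibrotic ligands, of 30 tested, 18 rose and 4 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.79. The profibrotic ligands and TGF-beta pathway list had camera adjusted p = 1.81e-05, and adjusted p = 0.228 with an estimated correlation. Its members included Spp1 5.74 ± 0.14, Ereg 5.19 ± 0.17 and Pdgfb 2.34 ± 0.08. For oxidative phosphorylation subunits, of 36 tested, 32 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.65. The nuclear oxidative phosphorylation subunits list had camera adjusted p = 3.00e-07, and adjusted p = 0.196 with an estimated correlation. For cholesterol synthesis, of 23 tested, 1 rose and 21 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -1.01. The cholesterol synthesis list had camera adjusted p = 3.00e-07, and adjusted p = 0.237 with an estimated correlation. Its members included Idi1 at -2.03 ± 0.09. For immediate early genes, of 29 tested, 5 rose and 22 fell (7 and 22 adjusted over the list alone), with a median log2 fold change of -1.30. The immediate early and heat shock list had camera adjusted p = 3.12e-05, and adjusted p = 0.331 with an estimated correlation. Its members included Fos -2.03 ± 0.08 and Ier2 -2.29 ± 0.07. For lysosome and autophagy genes, of 31 tested, 20 rose and 4 fell (20 and 4 adjusted over the list alone, camera adjusted p = 2.03e-04, adjusted p = 0.228 with an estimated correlation), and for MHC class II, of 9 tested, 1 rose and 8 fell (1 and 8 adjusted over the list alone, camera adjusted p = 9.95e-04, adjusted p = 0.282 with an estimated correlation). The unfolded protein response, higher in OG CD44- cells, did not pass by camera in CD44+ cells: of 30 tested, 15 rose and 9 fell (15 and 10 adjusted over the list alone, camera adjusted p = 0.118, adjusted p = 0.331 with an estimated correlation). It passed by fry (adjusted p = 8.14e-09).

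Endothelial markers were lower in OG than in R26 CD44+ cells, prefixes whose genotypes are inferred: of 23 tested, 1 rose and 20 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -2.10. The endothelial cell markers list had camera adjusted p = 3.12e-05, and adjusted p = 0.236 with an estimated correlation. Its members included Cdh5 going from 22.4 ± 2.75 to 2.53 ± 0.949 CPM and Sema3c at 1.68 ± 0.10. For fibroblast markers, of 27 tested, 9 rose and 9 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.13. The fibroblast and mural cell markers list had camera adjusted p = 0.907, and adjusted p = 0.969 with an estimated correlation. Its members included Sparc at 1.49 ± 0.06 and Dcn at -1.16 ± 0.10, and there the camera direction was up while the median lay below 0. Ciliated and basal markers were higher in OG CD44+ cells. For ciliated markers, of 20 tested, 18 rose and 0 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 1.67. The ciliated cell markers list had camera adjusted p = 2.87e-06, and adjusted p = 0.275 with an estimated correlation. For basal cell markers, of 10 tested, 6 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.228 with an estimated correlation). No further list of other-type markers passed at the preset correlation. By fry, mesothelial, macrophage and erythroid lists pointed down, and neutrophil and neuroendocrine lists pointed up (adjusted p = 1.86e-05 to 0.0288). Member calls went against the fry direction for 8 rose and 5 fell of 24 macrophage markers, with a median of 0.32. They also did for neuroendocrine markers, where 2 rose and 3 fell of 8. Other large increases were Cd177 6.18 ± 0.27, Ptprn 5.23 ± 0.11, Kif1a 5.12 ± 0.10, Tenm4 5.01 ± 0.10 and Itga2 4.15 ± 0.21, and other large decreases were Acoxl -4.67 ± 0.18, Anpep -4.25 ± 0.16, Itih4 -4.11 ± 0.11, Rerg -4.07 ± 0.11, Nrn1 -4.03 ± 0.28 and Gem -3.87 ± 0.15. Cd44 changed by 0.96 ± 0.08, Epcam by 0.87 ± 0.05, Itgb4 by 2.76 ± 0.12, Cd200 by -0.78 ± 0.05 and Pecam1 by -2.36 ± 0.35. Ptprc was at -0.61 ± 0.34 (adjusted p = 0.115 by edgeR), and at -0.97 without OG animal 3 CD44+ (adjusted p = 0.0109, and up to 0.836 over all alternatives). edgeR called 5358 genes higher and 5368 lower, 1566 and 2311 at least 2-fold, and 2154 and 2625 past the 1.5-fold minimum. Of the genes higher in OG CD44- cells, 4514 were also higher in OG CD44+ cells (2111 for independent lists), and of the lower ones 3898 were also lower (1589), in libraries from the same animals.

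The interaction asks whether the CD44 difference itself differed between the prefixes, as the CD44+ minus CD44- change in OG less that in R26. OG reads as mutant and R26 as control only under the unverified reading above. Endothelial genes had a lower CD44 change in OG than in R26: of 23 tested, 0 had a higher and 23 a lower CD44 change in OG (the same numbers adjusted over the list alone), with a median log2 difference of -2.71. The endothelial cell markers list had camera adjusted p = 3.69e-16, and adjusted p = 0.128 with an estimated correlation. Its members included Cdh5 -4.28 ± 0.28 and Plvap -3.16 ± 0.34. Fibroblast genes rose less in OG: of 27 tested, 1 had a higher and 18 a lower CD44 change in OG (1 and 20 adjusted over the list alone), with a median log2 difference of -1.48. The fibroblast and mural cell markers list had camera adjusted p = 2.08e-08, and adjusted p = 0.376 with an estimated correlation. Its members included Dcn -2.72 ± 0.16 and Postn -1.81 ± 0.19. For NRF2 genes, of 26 tested, 0 had a higher and 17 a lower CD44 change in OG (the same numbers adjusted over the list alone), with a median log2 difference of -0.40. The NRF2 and oxidative stress list had camera adjusted p = 1.22e-06, and adjusted p = 0.35 with an estimated correlation. Its members included Slc7a11 -3.00 ± 0.23, Srxn1 -1.63 ± 0.10 and Gclm -1.43 ± 0.12. For the AT2 list, of 30 tested, 1 had a higher and 16 a lower CD44 change in OG (2 and 16 adjusted over the list alone), with a median log2 difference of -0.40. The AT2 identity and surfactant list had camera adjusted p = 1.10e-04, and adjusted p = 0.531 with an estimated correlation. Its members included Hc -1.36 ± 0.09, Lamp3 -0.92 ± 0.08 and Ctsh 0.81 ± 0.09. For AT1 markers, of 22 tested, 2 had a higher and 11 a lower CD44 change in OG (3 and 13 adjusted over the list alone), with a median log2 difference of -0.43. The AT1 markers list had camera adjusted p = 2.99e-04, and adjusted p = 0.478 with an estimated correlation. Its members included Spock2 at -2.04 ± 0.12. For transitional markers, of 34 tested, 8 had a higher and 13 a lower CD44 change in OG (8 and 14 adjusted over the list alone), with a median log2 difference of -0.14. The transitional alveolar list had camera adjusted p = 0.514, and adjusted p = 0.884 with an estimated correlation. Its members included Plaur -2.36 ± 0.19 and Cldn4 -1.72 ± 0.17. Large positive values were Slc7a2 1.64 ± 0.28, Rgs16 1.55 ± 0.40, Tgfbi 1.48 ± 0.30, Muc5b 1.38 ± 0.30 and Lpl 1.36 ± 0.38. Further large negative ones were Tnxb -3.38 ± 0.27, Jchain -2.84 ± 0.84 and Igkc -2.76 ± 0.71. Jchain lost its call without any 1 of 7 libraries (R26 CD44- of animals 8, 7, 2 and 1, R26 CD44+ of animals 2 and 1, and OG CD44- of animal 3), with adjusted p of 5.08e-05 to 0.0884 over all alternatives.

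With genotype still an inference, Sftpc was at -0.25 ± 0.16 in the interaction (adjusted p = 0.278 by edgeR), and at -0.24 with the animals as a replicate block (adjusted p = 0.0498). Cd44 was at 0.19 ± 0.11 (adjusted p = 0.215), and its value passed the threshold at 0.34 with OG animal 7 CD44- as the scaling reference (adjusted p = 0.0243). It also passed without R26 CD44- of animal 2 or R26 CD44+ of animal 7, 2 or 1. Over all alternatives its adjusted p ran from 9.06e-04 to 0.338. Cd200 was at -0.25 ± 0.07 (adjusted p = 0.0153) and lost its call under DESeq2 size factors (adjusted p = 0.0693), with OG references, and without any 1 of the 8 R26 libraries. Over all alternatives its adjusted p ran from 0.0019 to 0.386. edgeR called 1019 genes higher and 2806 lower, 149 and 1082 at least 2-fold, and 55 and 613 past the 1.5-fold minimum. The balance between higher and lower genes followed the scaling reference: with OG animal 7 CD44- as the reference, 2369 were higher and 1697 lower, and the median gene moved by 0.15 on the log2 scale. Without any 1 of the 8 R26 libraries, 1720 to 2419 genes were higher, and 1651 to 1835 were lower without any 1 of them other than R26 CD44+ of animal 2.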

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

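All tests of explanations in this part were chosen after the results were seen, and 3 of them were revised after a first outcome. For the AT2 share, the lists with the highest and lowest medians were compared first, then the same after leaving out genes at 3 or fewer counts, where quartiles overlapped, and last any pair of lists. For OG animal 3, a bound on the number of lists left more cells of other types undecided, and the explanation was then narrowed to every other type. For scaling, the 16 possible TMM references were added, with the same outcome. A test of the depth of the OG animal 3 library decided nothing and was dropped.

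Other-cell-type markers moved with CD44+ sorting, although the gate removes cells with CD45, CD31 or CD104 and asks for Epcam, an epithelial surface protein, and high CD200. Whether fibroblasts or other cells without Epcam passed it was not measured. In R26 cells, all 11 other-type lists had medians above 0, which fits more cells of every other type in the CD44+ sort; 24 of the 27 fibroblast markers reached 1 CPM in R26 CD44- cells as well. For a lower share of AT2 cells with the rest in fixed proportions, the fibroblast median exceeded the ciliated median by 1.06 with quartiles apart. This cannot decide it: the pair was taken as the widest gap, and markers that AT2 cells also make would rise less. In OG cells only 9 of the 11 medians lay above 0, and lymphocyte and endothelial medians differed by 2.56. Endothelial markers fell there, with a median of -0.68 (2 rose and 12 fell of 23). By camera that fall lost its call with a replicate block, so it decides neither explanation. Esam also fell from R26 CD44- to CD44+ cells (117 to 92.2 CPM), as AT2 genes did. Expression of these genes by CD44+ AT2 cells themselves stays open and was not tested in bulk libraries.

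Immediate early genes were lower in OG libraries. The choice of scaling is argued against, since it moved the median gene by at most 0.12. Handling that differed between the prefixes cannot be told apart from the prefix itself: the list's mean level was at least 1.03 log2 CPM higher in R26, and the widest range within a group was 0.407. A difference by genotype, if the prefixes mark it, stays open and untested.

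OG animal 3 CD44+ stood apart from the other OG CD44+ libraries. Its mean level was the highest for 7 of the 11 other-type lists, with fibroblast markers at 6.20 against 5.65 to 5.72 log2 CPM, but the lowest for ciliated markers, at 4.41 against 4.79 to 4.82. The 7 were basal, endothelial, erythroid, fibroblast, lymphocyte, macrophage and mesothelial lists. Club and neuroendocrine markers were also lowest there, by less, at 5.97 against 6.17 to 6.34 and 1.67 against 1.69 to 1.87. More cells of every other type in that library is therefore argued against, while more cells of only some types stays open. No biological explanation was tested, since the labels give this animal nothing of its own.

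Of 496 groups of 4 values tested, 50 (10.1%) had a library far from the other 3 by Dixon's ratio, where chance gives about 1 in 20. The values are CPM of that library. In OG CD44+ cells, animal 3 stood apart for Ptprc 8.63, Pecam1 7.89, Igha 2029.8, Jchain 402, Igkc 1530.3, Ighg2c 55.3, Axl 45.5, Slc7a11 315, Igfbp4 120.1, Mmp2 153, Col3a1 1024, Eln 1118, Aqp5 631, Kif1a 306, Eno1 60.8, Cd177 129, Lpl 66.5. In OG CD44+ cells, animal 5 stood apart for Ereg 44.0. In OG CD44+ cells, animal 7 stood apart for Insig1 57.5. In OG CD44- cells, animal 3 stood apart for Igha 66.7, Jchain 15.2, Acoxl 72.6, Mme 239, Ccn2 47.8, Srxn1 653, Herpud1 178, Tgfbi 29.8. In OG CD44- cells, animal 5 stood apart for Trib3 117. In OG CD44- cells, animal 6 stood apart for Ptprc 0.717, Kif1a 408, Cdkn1a 291. In OG CD44- cells, animal 7 stood apart for Krt19 412. In R26 CD44+ cells, animal 2 stood apart for Ptprc 15.4, Sftpc 72715, Lyz2 23629, Pdgfb 25.9, Tmem42 32.5, Sfta2 104, Etv5 791, Aqp5 417, Bex2 48.1. In R26 CD44+ cells, animal 8 stood apart for Cdh16 44.8, Spock2 184, H2-Ab1 474. In R26 CD44- cells, animal 2 stood apart for Axl 4.08. In R26 CD44- cells, animal 7 stood apart for Dlk1 0.0658, Krt19 58.4, Notum 29.9. In R26 CD44- cells, animal 8 stood apart for Sftpd 2505. In OG CD44- cells, the 10 most abundant genes took 15.8% of counts in animal 6 and 16.6% to 16.7% in the others.

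The CD44 difference differed between the prefixes, whose genotypes are inferred, by edgeR's interaction test, for 28 named genes. The log2 values, OG less R26, were positive for Epcam 0.44, Itgb4 0.89, Slc7a2 1.64, Rgs16 1.55, Tgfbi 1.48, Muc5b 1.38, Lpl 1.36, Ctsh 0.81. They were negative for Cd200 -0.25, Ptprc -3.39, Pecam1 -2.65, Tnxb -3.38, Slc7a11 -3.00, Jchain -2.84, Igkc -2.76, Dcn -2.72, Hc -1.36, Lamp3 -0.92, Spock2 -2.04, Plaur -2.36, Cldn4 -1.72, Srxn1 -1.63, Gclm -1.43, Cdh5 -4.28, Plvap -3.16, Postn -1.81, Ccnb1 -2.30, Pgk1 -1.83. By camera at the preset correlation, 15 lists differed, none of them with an estimated correlation. Their median log2 values were -0.40 for AT2 identity and surfactant, -0.43 for AT1 markers, -0.16 for unfolded protein response and ER stress, 0.19 for cholesterol synthesis (SREBP2), 0.11 for glycolysis and hypoxia, 0.028 for nuclear oxidative phosphorylation subunits, -0.97 for cell cycle, -0.40 for NRF2 and oxidative stress, 0.25 for immediate early and heat shock (dissociation stress), 0.42 for club and secretory cell markers, 0.36 for ciliated cell markers, -1.48 for fibroblast and mural cell markers, -2.89 for mesothelial cell markers, -2.71 for endothelial cell markers, -1.46 for macrophage and monocyte markers. Of these, cell cycle, ciliated, immediate early, oxidative phosphorylation and unfolded protein response calls were lost without at least 1 library. By fry, calls were lost for cholesterol synthesis (adjusted p = 0.108), glycolysis and hypoxia (adjusted p = 0.0646), nuclear oxidative phosphorylation subunits (adjusted p = 0.398), cell cycle (adjusted p = 0.108), immediate early and heat shock (adjusted p = 0.324), club and secretory cell markers (adjusted p = 0.0556) and ciliated cell markers (adjusted p = 0.196).

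Other splits of the same libraries did not reach the real counts of called genes, and the real split was the 1 of 35 with as many in each comparison. In OG CD44+ against CD44-, 7815 genes were called and 0 in the highest other split. The figures were 5750 and 885 for R26, 10705 and 0 for CD44- cells between prefixes, 10726 and 170 for CD44+ cells between prefixes, and 3825 and 0 for the interaction. Between prefixes, 1 of 35 is the lowest share these splits can give. Other splits mixed libraries of both prefixes, which raises their spread, so they argue only against no difference at all between prefixes. For the interaction, whole animals moved between prefixes, so the splits do not test it apart from the prefix difference. Chance is not excluded for the interaction by them. In the CD44 comparisons each animal gave both sorts, and 8 of the 35 splits put the 2 libraries of every animal on different sides. The other splits of that kind called at most 0 genes in OG and 1 in R26, and they are too few for a share under 0.05.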

How the results depend on the processing

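The TMM reference tests, voom with 1 weight per group and the fits without OG animal 3 were chosen after seeing the data. No gene called both in the main fit and under an alternative had opposite directions in them. Apart from named genes, genes that lost their call were not checked for direction. With a 1.5-fold minimum, genes higher and lower numbered 1483 and 362 in OG CD44+ against CD44-, 2026 and 9 in R26, 2551 and 2095 for OG against R26 in CD44- cells, 2154 and 2625 in CD44+ cells, and 55 and 613 for the interaction, since small changes no longer count. In R26 CD44+ against CD44-, 1353 were lower in a fit of only those 8 libraries; the cause was not tested. TMM scales to 1 library, an R26 CD44+ one by default, and leaving out any R26 library moved that choice to OG animal 7 CD44+. With OG animal 7 CD44+ as the reference, 4007 genes were lower in R26 CD44+ cells and 1978 higher in the interaction; with OG animal 7 CD44-, 4824 were lower in R26 CD44+ cells, and 2369 were higher and 1697 lower in the interaction. Leaving out 1 library gave 2307 to 4429 lower in R26 CD44+ cells, and 824 to 2419 higher and 1651 to 2865 lower in the interaction. The share of higher genes among calls was 58.4% in R26 CD44+ against CD44-, 48.0% under DESeq2 size factors, and 38.2% and 43.4% with the OG references. For the interaction it was 26.6%, 39.1% under size factors, 38.4% under the DESeq2 test, and 58.3% and 51.4% with the OG references, so which direction holds more genes is not settled. Without both libraries of OG animal 3, 3018 were higher and 3608 lower in OG CD44+ cells.

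Named genes kept their side of the threshold in 3335 of the 3360 leave-one-out fits, with 15 calls lost and 10 gained. Lost calls were Cd200 and Jchain in the interaction (adjusted p over all alternatives 0.0019 to 0.386 and 5.08e-05 to 0.0884), and gained ones Cd44 there, Epcam in R26, and Pecam1 and Ptprc in OG CD44+ cells. Macrophage markers between prefixes in CD44+ cells pointed down by fry (adjusted p = 0.014) and up by camera (adjusted p = 0.644); the cause was not tested. With the animals as a replicate block, 3788 genes were higher and 4785 lower in OG CD44+ cells, 3629 and 2969 in R26, and 1449 and 3525 in the interaction. The block brought Sftpc in the interaction past the threshold (-0.24, adjusted p = 0.0498), ended the endothelial call in OG CD44+ cells (adjusted p = 0.079) and added MHC class II and lymphocyte calls in the interaction (adjusted p = 0.0374 and 0.028). It changed no other call of a named gene or list. No paired analysis was possible for OG against R26 because the prefixes hold different animals. Leaving out 1 library ended 3 list calls in OG CD44+ against CD44- (basal, endothelial and sorting antigen lists), 2 in R26 (MHC class II and immediate early lists), 0 between prefixes and 5 in the interaction (cell cycle, ciliated, immediate early, oxidative phosphorylation and unfolded protein response lists). It gained 2 calls in OG (oxidative phosphorylation, Wnt and Notch), 1 in R26 (sorting antigens) and 3 in the interaction (lysosome, MHC class II, lymphocyte). Between prefixes it gained 1 in CD44- cells (endothelial) and 1 in CD44+ cells (cell cycle). By fry, 7 calls ended in the interaction, 1 in R26 (immediate early, adjusted p = 0.0532) and 0 in the others. Calls gained by fry numbered 4 in the interaction, 4 in R26 and 3 in OG CD44+ against CD44-. Between prefixes fry gained 11 in CD44- cells and 9 in CD44+ cells, besides the macrophage list. Size factors ended 1, the unfolded protein response in the interaction (adjusted p = 0.111). Depth limits genes with 3 or fewer counts over a group, for which no fold change is given.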

Other observations

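In OG CD44+ against CD44- cells, MHC class II, NF-kappaB and sorting antigen lists passed the threshold at the preset correlation, and the Wnt and Notch and glycolysis lists did not. For MHC class II, of 9 tested, 1 rose and 7 fell (the same numbers adjusted over the list alone), with a median log2 fold change of -0.43. The MHC class II list had camera adjusted p = 0.0163, and adjusted p = 0.39 with an estimated correlation. For NF-kappaB and inflammatory genes, of 33 tested, 17 rose and 6 fell (18 and 6 adjusted over the list alone), with a median log2 fold change of 0.88. The NF-kappaB and inflammatory cytokines list had camera adjusted p = 0.00166, and adjusted p = 0.39 with an estimated correlation. For Wnt and Notch genes, of 25 tested, 13 rose and 8 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.30. The Wnt and Notch pathway genes list had camera adjusted p = 0.0563, and adjusted p = 0.292 with an estimated correlation. For glycolysis and hypoxia, of 25 tested, 13 rose and 6 fell (13 and 7 adjusted over the list alone), with a median log2 fold change of 0.18. The glycolysis and hypoxia list had camera adjusted p = 0.13, and adjusted p = 0.345 with an estimated correlation. The Wnt and Notch list passed by fry (adjusted p = 5.36e-04) and without any 1 of 7 libraries (adjusted p = 0.0326 to 0.0493). For the list of 6 sorting antigens, of 6 tested, 4 rose and 1 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.55. The sorting antigens list had camera adjusted p = 0.0432, and adjusted p = 0.126 with an estimated correlation. That call was lost without any 1 of 7 libraries (adjusted p = 0.0539 to 0.0743).

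Pgk1 and Eno1, glycolytic enzymes with many processed copies in the genome, had low counts for such genes. Pgk1 was at 6.001 ± 1.13 CPM in R26 CD44-, 6.96 ± 1.246 in R26 CD44+, 83.0 ± 9.84 in OG CD44- and 27.5 ± 0.811 in OG CD44+ cells. Eno1 was at 8.83 ± 0.367, 12.0 ± 2.19, 45.4 ± 1.80 and 68.5 ± 5.18 CPM in the same order. How reads shared with copies were counted is not stated, so these values are uncertain.

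Mitochondrial messenger RNA took 2.86% ± 0.26 of counts in R26 CD44- cells, 5.47% ± 0.689 in R26 CD44+ cells, 1.61% ± 0.13 in OG CD44- cells and 2.13% ± 0.132 in OG CD44+ cells (SD, n = 4). Identifier 100861531 took 5.36% ± 0.434, 6.53% ± 0.827, 6.89% ± 0.628 and 11.1% ± 0.622 in the same order.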
